A study of Mus musculus with 24 samples.

How the data were processed

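RNA of epithelial cells isolated from the mouse cecum was measured with NanoString nCounter codesets, in which each target RNA is captured by its own probe pair and its color-coded reporters are counted on a lane without amplification. Per the labels, cecum pieces were opened, kept on ice in a cell recovery solution and shaken to release the epithelium, and total RNA was taken from the released cells without a sorting step. Of the 12 mice, 4 carried 2 intact copies of Ptpn2 (WT), 4 were heterozygous (HET) and 4 were homozygous for the constitutive deficiency (KO). Every mouse was 21 days old. The RNA of each mouse was run on 2 codesets, named A and B here, which gave 24 samples. The labels put replicate 1 of each genotype in litter 1, replicate 2 in litter 2 and replicates 3 and 4 in litter 3. WT replicate 4 and HET replicate 4 were male and the other mice female. The values of a Y-linked target, Uty, went with these labels, at 258.8 and 264.9 normalized counts in the males and at most 5.6 in the 10 females.

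The signal values used were the normalized counts the authors deposited for each codeset. Per the series' design text, the authors normalized the panels separately in nSolver 4.0 before consolidating them, and added 30 custom targets to each panel. The scaling factors, background setting and reference genes were not given in the sources used here. Each codeset listed 796 targets and 14 control rows. The values of codeset A had a floor of 1 or of the lane's own scaling step, as background-subtracted counts would, and those of codeset B stopped at a lane-specific floor of 8.40 to 15.29. The deposited consolidated table names its 12 value columns in a way that matches no sample label, so these columns were not used, and the values of the 2 codesets took the place that had been planned for the consolidated table. The authors' deposited tables of log2 fold changes and p-values for KO and HET against WT were used for comparison. These cover 1398 rows each. The kind of adjusted p in the KO table is not stated, but its values are those that a Benjamini-Yekutieli adjustment of its p-values gives. The column name of the HET table gives the adjustment as Benjamini-Yekutieli.

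Total normalized counts per lane ranged from 356483 to 450355 for codeset A and from 543966 to 842619 for codeset B. The median gap between the lowest distinct values of a lane was taken as what 1 count was multiplied by. This step was 0.81 to 1.17 in 11 lanes of codeset A and 5.65 in KO replicate 3. In codeset B it was 0.88 to 1.15 in 11 lanes and 4.11 in KO replicate 3. Divided by these steps, the lanes of KO replicate 3 held about 69103 and 132352 counts, against 307313 to 474392 and 555061 to 792575 in the other lanes, so its low values are the least precise of the study. In that mouse 37.8% of the codeset A targets lay at the floor, against 16.6% to 28.9% in the others. Because whole counts could not be recovered after background treatment, no count model was used and the precision was taken from the spread between mice. Because the floor differed between lanes, the change of a target at the floor in some mice can be understated or overstated.

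Values were turned into log2(value + 1), and a target on both codesets entered as the mean of its log2 values, so each mouse gave 1 value per target. The 30 housekeeping targets and the control rows were left out, which left 1383 endogenous targets, of which 168 were on both codesets. Over these 168, the KO minus WT differences of the 2 codesets had a correlation across targets of 0.86, or 0.97 over the 90 with a mean of at least 100 in each; targets are not independent replicates. No value of one codeset was set against a value of the other as a level. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to all 12 mice with genotype as the only factor, for KO minus WT, HET minus WT, KO minus HET, and HET minus the mean of KO and WT. Adjusted p-values are Benjamini-Hochberg values over all targets with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low targets. On simulated data with 200 of 1383 targets changed between KO and WT, the fit called 61.1% of changes of log2 1 and 90.4% of changes of log2 2, and 4.8% of its calls were false. The simulated errors were normal and independent between targets and mice, with no floor and no litter effect. These rates need not hold for the real data, where targets move together.

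Before the data were examined, 28 gene lists were fixed and matched to target names without regard to case. The 23 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. camera with an estimated correlation and fry were the alternatives. A list score is the mean log2 value of the members in a mouse, relative to the WT mean, and its group difference was tested by a two-sided exact permutation test, whose smallest possible p with 4 mice per group is 0.0286. Named genes followed a rule set beforehand. For KO against WT these were Ptpn2, the 10 largest increases and 10 largest decreases among targets past the threshold whose 4 KO values all lay on one side of the 4 WT values, and up to 4 members with the smallest p of each list described. For HET against WT and KO against HET these were the 5 largest increases and 5 largest decreases under the same conditions, or, with fewer than 5 targets past the threshold, the 5 with the smallest p. Ptpn2 itself was not analysed here, so the genotype labels have no check from the targeted gene. Which lists are described with members was decided after the first results had been seen. The endothelial list was for a time set aside after some of its members had reversed under other settings, and was then restored. The lists not described with members are given by their medians. Genes named outside this rule are said to be so. A gene that the rule would name is not reported here.

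The replicate numbers pair the mice because the labels give the litters. Deviations from the group means had a mean correlation of 0.09 over the 18 pairs of littermates of different genotype and −0.05 over the 30 pairs from different litters. The fit with litter as a fixed block was planned as an alternative. The other alternatives chosen before the data were examined were pseudocounts of 10 and 0.5, a minimum mean of 20, quantile normalization, median centring, litter as a random block, sex as a covariate, the males left out, only the 2 groups compared, limma-trend with robust eBayes, array weights, Benjamini-Yekutieli adjustment, each mouse left out, litter 3 alone and each codeset alone. A common floor for all lanes, set to the highest of their smallest values above the floor (6.62 in codeset A and 49.3 in codeset B), the joint removal of KO replicate 3 and WT replicate 1, and matching of list members by RefSeq accession (GRCm38.p6 gene table, 1365 of 1383 targets matched) were added after the data were seen. No probe positions were used. No 2 mice had identical values.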

Results

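Ptpn2 encodes a protein tyrosine phosphatase that removes phosphate from JAK and STAT proteins and so dampens cytokine signalling. The series asked how its constitutive loss alters targeted transcripts of the cecal epithelium in mice of 21 days, an age chosen because homozygous mutants look normal at birth and die a few weeks later. Isolated cecum epithelial cells of 4 WT, 4 HET and 4 KO littermates from 3 litters were profiled for 1383 endogenous targets on 2 nCounter codesets. Total normalized counts per lane lay between 356483 and 450355 for codeset A and between 543966 and 842619 for codeset B. The values of KO replicate 3 moved in steps of 5.65 and 4.11 per count, and those of every other lane in steps of at most 1.17, so this mouse had the fewest counts. The targeted gene, Ptpn2, was not analysed here. On the first principal component, which held 39.6% of the variance, the KO mice lay between −27.60 and −11.60, the HET mice between 1.43 and 12.95, and WT replicates 2, 3 and 4 between 11.74 and 17.68. WT replicate 1 lay at −10.88, next to the KO mice.

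The comparison of KO with WT asks which transcripts differ when both copies of Ptpn2 are lost. The cells isolated from KO mice carried more transcripts of interferon-stimulated genes and of some chemokines. Because these cells were not sorted, which cell type carried the transcripts was not measured. The largest increases were Ifi44l, at 28.9-fold (log2 4.85 ± 1.05, SE), and Ifi44, at 21.2-fold (log2 4.40 ± 0.95), both interferon-induced. Cxcl9 and Cxcl10, ligands of the T-cell chemokine receptor CXCR3, rose 15.1-fold and 10.9-fold (log2 3.92 ± 0.78 and 3.44 ± 0.81). Ccl8, a monocyte-attracting chemokine, rose 6.31-fold (log2 2.66 ± 0.52) and was at the floor in 2 of 4 WT mice. The antiviral genes Oas2, Rsad2 and Ifit1 rose 9.46-fold, 6.22-fold and 6.12-fold. Isg15, which encodes a ubiquitin-like interferon-induced protein, went from 742 ± 714 normalized counts in WT to 4197 ± 1108 in KO (SD, n = 4 each), and Sp100, a nuclear body component, from 117 ± 99.8 to 538 ± 157. In limma their adjusted p-values lay between 0.00768 for Oas2 and Ifit1 and 0.0411 for Cxcl10. All 4 KO values of each were above all 4 WT values, which the rule for naming them required. Under a common floor for all lanes, 6.62 in codeset A and 49.3 in codeset B, the log2 changes of Ifi44l, Cxcl9, Cxcl10 and Ccl8 were 3.74, 3.00, 2.38 and 1.13. Ifi44 no longer passed under it (log2 4.30, adjusted p = 0.0542 in limma).

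The largest decreases were these. Wnt5a, a noncanonical Wnt ligand, fell from 20.9 ± 9.30 to 2.35 ± 2.22 normalized counts (log2 −2.80 ± 0.40, adjusted p = 0.00768 in limma) and was at the floor in 2 of 4 KO mice. Dclk1, a tuft cell marker in the intestinal epithelium, fell from 27.9 ± 14.3 to 4.73 ± 3.61. Fgf1 and Fgfr3, a fibroblast growth factor and a receptor of that family, were 3.71-fold and 3.46-fold lower (log2 −1.89 ± 0.44 and −1.79 ± 0.40). The kinase genes Stk26 and Map2k6 were 3.27-fold and 2.87-fold lower. Kdr, the VEGF receptor 2 gene, was 2.80-fold lower, from 14.1 ± 2.83 to 4.36 ± 0.91 normalized counts, so its level was low in all groups. Thbs1, Cxcr4 and Il1r1, which encode thrombospondin 1, the CXCL12 receptor and the interleukin 1 receptor, were 2.57-fold, 2.33-fold and 2.04-fold lower. The adjusted p-values of these 10 targets lay between 0.00768 and 0.0399 in limma. The rule for naming them required that KO and WT mice did not overlap. Dclk1, Fgf1, Kdr and Cxcr4 were at the floor in 1 KO mouse each. For Cxcr4 the difference was 0 under the common floor of 49.3, which lay above all its group means. Under the common floor of the codeset of each, Dclk1, Fgf1, Fgfr3 and Stk26 no longer passed (adjusted p = 0.0983, 0.0663, 0.06 and 0.103 in limma), and the log2 changes of Wnt5a, Stk26 and Kdr were −1.43, −1.03 and −0.96.

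**Figure D1:**
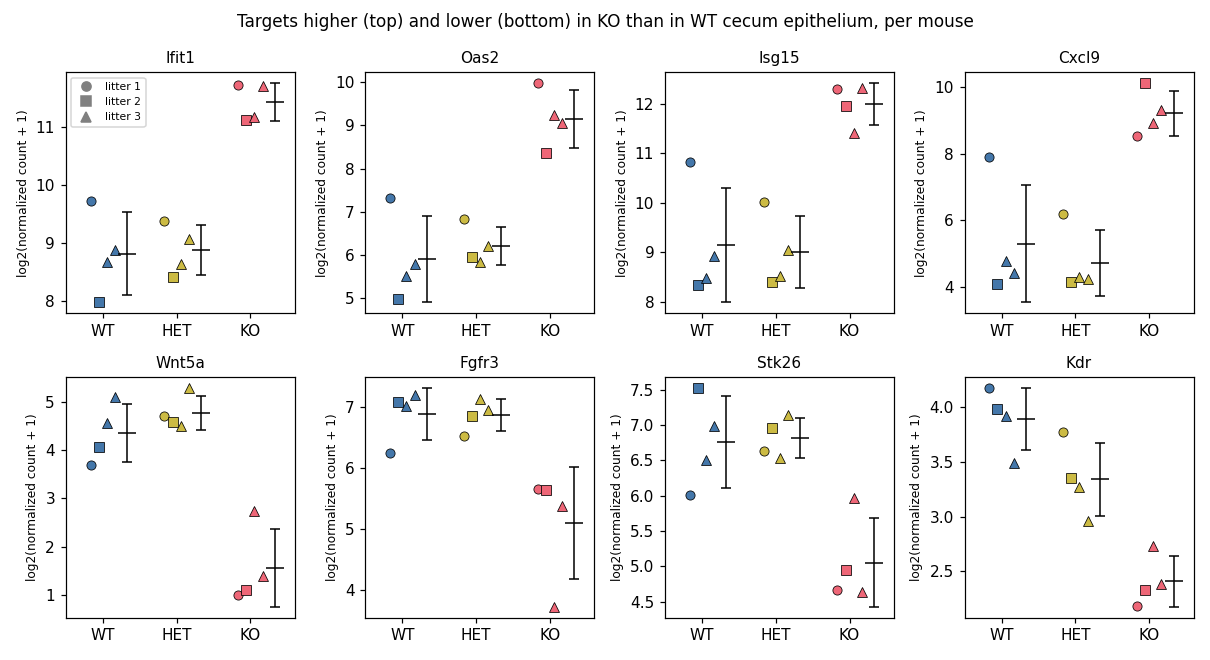
The vertical axes show log2(normalized count + 1) of 8 targets in each of 12 mice, with a marker shape per litter and a bar for the mean ± SD of 4 mice per genotype. Ifit1, Oas2, Isg15 and Cxcl9 lay higher in all 4 KO mice than in any WT mouse, and Wnt5a, Fgfr3, Stk26 and Kdr lay lower. This separation was a condition for naming these targets.

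In all, 48 of 1383 targets passed in limma for KO against WT, 36 of them higher and 12 lower in KO, and 241 had an unadjusted p under 0.05. The 4 KO values lay apart from the 4 WT values for 9.1% of targets, where chance gives 2.86%. With litter as a block, 86 targets passed, 68 higher and 18 lower, and these included all 48. The median over all targets was 0.08, and −0.06 after quantile normalization and −0.08 after median centring. The split into 36 higher and 12 lower was 39 and 42 after quantile normalization and 28 and 28 after median centring. The count was 114 without WT replicate 1 and 8, 8 and 7 without WT replicates 2, 3 and 4. It was 27 without HET replicate 4 and 15, 11, 27 and 31 without KO replicates 1, 2, 3 and 4. It was 9 with sex as a covariate, 1 without the 2 male mice, 3 when the HET mice were left out of the fit and 0 with the Benjamini-Yekutieli adjustment. The differences of the 48 targets, signed as in the fit, had a median of log2 0.93 between the single KO and WT mice of litter 1, with 47 of 48 in the same direction. The median was 1.91 in litter 2 and 1.86 in litter 3, with all 48 in the same direction in each. These mice had themselves chosen the targets, so the values describe the size per litter.

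The authors' deposited table for KO against WT lists 273 of 1398 rows with a p under 0.05, 178 higher and 95 lower, and no row with an adjusted p under 0.05. Its adjusted values have the Benjamini-Yekutieli form, which is stricter than the Benjamini-Hochberg one behind the 48 calls. With that adjustment the limma fit called 0 targets as well. In the authors' deposited table Kdr had a tied smallest adjusted p of 0.0577, with a log2 change of −1.69, and Ifit1 had a log2 change of 2.51 with an adjusted p of 0.0631. Ifih1 had the same adjusted p of 0.0577, with a log2 change of 1.21. All 48 targets called in limma had the same sign in the authors' deposited table.

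Of 23 lists tested in KO against WT, camera called 4, all higher, and 2 without WT replicate 4 or without KO replicate 2. After median centring it called 1. Some lists share members, so their shifts are not separate results in any comparison. Psmb8 and Psmb9 are in the interferon and MHC class I lists, and Cxcl9 and Cxcl10 in the interferon and cytokine lists. Stat2 and Socs1 are in the interferon and JAK-STAT lists. The interferon response genes had the smallest p. Of 34 measured members, 15 rose and none fell over all targets in KO against WT, and 29 rose when adjusted over the list alone. Beside Oas2, Rsad2 and Ifit1, Ifih1, which encodes the RNA sensor MDA5, rose 2.33-fold from 1219 ± 238 to 2812 ± 304 normalized counts (adjusted p = 0.00768 in limma). The median change was log2 1.64, and camera placed the list above the other targets (adjusted p = 7.23e-18). That call ended with an estimated correlation (adjusted p = 0.735 with an estimated correlation, which itself was 0.54), while fry gave an adjusted p of 0.0274. The mean log2 value of the list was 1.74 higher in KO than in WT, with a two-sided exact permutation p of 0.0286, the smallest possible, and 0.219 after adjustment over the 23 lists. With litter as a block, 26 members rose and fry gave an adjusted p of 0.00113. The median KO minus WT difference of the list was 0.63 in litter 1, 2.02 in litter 2 and 1.87 in litter 3. T and NK cell markers moved with this list, with a mean shift of 0.67.

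MHC class I presentation genes were shifted up as a list (adjusted p = 0.0207 with camera, 0.735 with an estimated correlation). None of the 10 measured members passed over all targets, and 6 rose when adjusted over the list alone. Over all targets 3 passed with litter as a block. The median was 0.04 in litter 1, 1.69 in litter 2 and 0.64 in litter 3. The immunoproteasome subunits Psmb8 and Psmb9 had log2 changes of 1.86 ± 0.65 and 1.63 ± 0.59, the class I heavy chain gene H2-D1 0.63 ± 0.23 and the light chain gene B2m 1.06 ± 0.38. MHC class II presentation genes had a median change of 1.53, but none of 10 members passed on either scale and the list did not pass (adjusted p = 0.117 with camera). With litter as a block 1 class II member passed and the list passed in camera (adjusted p = 0.0483) but not with an estimated correlation (adjusted p = 0.75 with an estimated correlation). Its median was −0.10 in litter 1, 3.87 in litter 2 and 1.15 in litter 3. Ciita, the master regulator of class II genes, had a log2 change of 2.20 ± 0.80, and H2-DMa and H2-DMb1, which encode the chaperone that loads class II peptides, 1.36 ± 0.63 and 1.43 ± 0.66. The spread was wide in WT, with WT replicate 1 at 405.3 normalized counts of Ciita against 23.3 to 62.6 in the other 3 WT mice.

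Cytokine and chemokine genes rose as a list (adjusted p = 8.58e-04 with camera, 0.735 with an estimated correlation). Of 39 measured members 5 rose over all targets and 7 when adjusted over the list alone, and none fell. The median was 0.32, and 0.014 under the common floor. Besides Cxcl9, Cxcl10 and Ccl8, these were Ccl5, which recruits T cells, at 4.40-fold (log2 2.14 ± 0.38, adjusted p = 0.0186), and Il1rn, the interleukin 1 receptor antagonist, at 3.73-fold (log2 1.90 ± 0.40, adjusted p = 0.0292, both in limma). Of the 31 NF-kB and TNF signalling genes only Icam1, an adhesion molecule, passed, at log2 1.92 ± 0.43, and 4 passed with litter as a block. Under the common floor Icam1 did not pass (log2 0.47, adjusted p = 0.103 in limma). When adjusted over the list alone 5 rose and 1 fell, the list did not pass (adjusted p = 0.133 with camera), and its median of 0.26 turned to −0.03 after median centring. Traf1, at the floor in 3 KO mice, had a log2 change of −1.29 ± 0.32, Traf6 of 0.54 ± 0.14 and Ripk2 of 0.99 ± 0.27.

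Of 22 JAK-STAT components, the pathway that Ptpn2 acts on, Stat2 passed, at 3.27-fold (log2 1.71 ± 0.37, adjusted p = 0.0292 in limma), and 3 components passed with litter as a block. Under the common floor Stat2 did not pass (log2 1.71, adjusted p = 0.0542 in limma). Stat3 had a log2 change of 0.58 ± 0.18 (adjusted p = 0.105) and the feedback inhibitors Socs1 and Socs3 of 2.68 ± 0.82 and 2.37 ± 0.85 (adjusted p = 0.106 and 0.161), all in limma and none past the threshold. The list did not pass (adjusted p = 0.285 with camera), and its median of 0.13 turned to −0.06 after quantile normalization and −0.07 after median centring. None of the 10 genes of a STAT3-linked epithelial response passed over all targets, and 1 rose when adjusted over the list alone, as 1 did over all targets with litter as a block. Nos2, the inducible nitric oxide synthase, had a log2 change of 2.33 ± 0.63, and Pim1 of 0.77 ± 0.38.

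Markers of cells other than epithelium were measured because the cells were not sorted. T and NK cell markers rose as a list (adjusted p = 0.0117 with camera, 0.735 with an estimated correlation), with a median change of 0.39 over 29 members that turned to −0.04 after median centring and was 0.028 under the common floor. The median was −0.01 in litter 1, 0.85 in litter 2 and 0.70 in litter 3. Only Cd8a, a coreceptor of cytotoxic T cells, passed over all targets, going from 15.7 ± 7.60 to 49.3 ± 24.3 normalized counts with 2 WT mice at the floor, and 7 rose when adjusted over the list alone. Over all targets 5 rose with litter as a block. Under the common floor of 49.3, about as high as the KO mean of Cd8a, most of its difference was removed by the setting itself. Cd8a did not pass there (log2 0.21, adjusted p = 0.566 in limma). The cytotoxic granule genes Gzma and Gzmb had log2 changes of 3.32 ± 0.85 and 2.42 ± 0.64, and Cd7 of 1.41 ± 0.39. No member of the 16 monocyte, macrophage and dendritic cell markers or of the 17 neutrophil and mast cell markers passed, over all targets or when adjusted over the list alone, and neither list did (adjusted p = 0.328 with camera for each). With litter as a block 1 monocyte, macrophage and dendritic cell marker rose and 1 fell. C1qa, a complement gene of macrophages, had a log2 change of −0.67 ± 0.20 and Cd14 of 0.98 ± 0.40. Ly6g, a neutrophil marker, had 2.71 ± 0.86, and Kit, a mast cell receptor, −0.87 ± 0.27. The 13 B and plasma cell markers had a median change of 0.03, which turned to −0.13 after quantile normalization and −0.40 after median centring.

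Genes of stroma, Wnt signalling and epithelial lineages went both ways or stayed below the threshold. Among 30 extracellular matrix and stromal genes Thbs1 fell, over all targets and when adjusted over the list alone. Their median was 0.24, and −0.045 after quantile normalization, while their mean was −0.14, and the list did not pass (adjusted p = 0.522 with camera). Of 7 endothelial markers Kdr fell over all targets, as it did when adjusted over the list alone, and the list did not pass (median −0.04, adjusted p = 0.518 with camera). Flt4, the VEGF receptor 3 gene, had a log2 change of 0.47 ± 0.43 that turned to −0.047 without KO replicate 3. Vwf, the von Willebrand factor gene, had 0.20 ± 0.18, which turned to −0.24 after median centring, and Nos3, the endothelial nitric oxide synthase gene, 0.43 ± 0.44, which turned to −0.041 after quantile normalization; Nos3 was near the floor throughout. Of 41 Wnt genes, Wnt5a fell and Sfrp1, a secreted Wnt antagonist, rose 5.21-fold (log2 2.38 ± 0.55, adjusted p = 0.0384 in limma, and 0.0725 under the common floor), while Tcf7l1 had a log2 change of −1.59 ± 0.50 (adjusted p = 0.113). None of 11 stem and progenitor markers passed. Among them LGR5, a marker of crypt stem cells, had a log2 change of −0.80 ± 0.25 (adjusted p = 0.107 in limma) and Myc of 0.60 ± 0.24. Of 38 cell cycle genes only Ccnd2, cyclin D2, passed, at 1.82-fold, and the list had a median of 0.14 while its test pointed down (adjusted p = 0.977 with camera). The 7 Paneth cell markers all had lower means in KO, but none passed, and the defensin DEFA6 varied so widely that its log2 change was −3.75 ± 1.81.

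**Figure D2:**
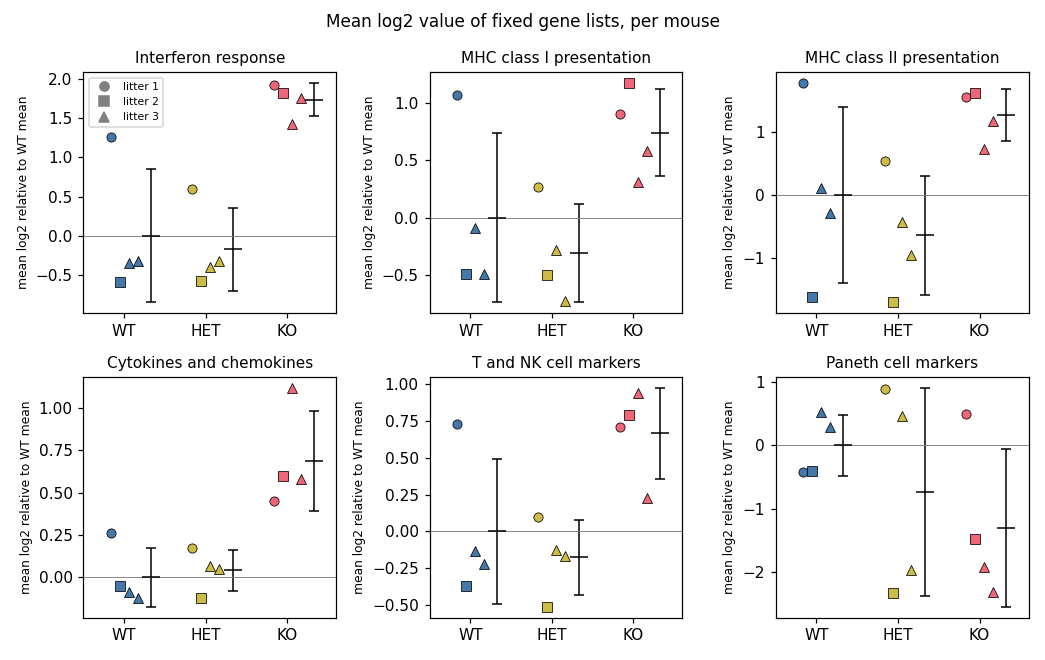
The vertical axes show the mean log2 value of 6 gene lists in each of 12 mice, relative to the mean of the WT mice, with a marker shape per litter and a bar for the mean ± SD of 4 mice per genotype. For the interferon list the KO mice lay between 1.43 and 1.92, WT replicate 1 at 1.26 and the other WT mice between −0.58 and −0.33.

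The comparison of HET with WT asks whether losing 1 copy alters the profile. No target passed in limma, and 12 of 1383 had an unadjusted p under 0.05, 9 higher and 3 lower. The count stayed 0 with litter as a block, where 15 targets had an unadjusted p under 0.05. The targets with the smallest p did not pass. Flnc, an actin crosslinker, had 3.05 ± 2.32 normalized counts in WT and 8.74 ± 3.38 in HET, and Kdr 14.1 ± 2.83 and 9.35 ± 2.48 (log2 −0.55). Ret was at the floor in all 4 WT mice, as was Pstpip1, and Sh2d1a in 3 of 4, so no fold is given for these 3. The authors' deposited table for HET against WT lists 19 rows with a p under 0.05 and no row with an adjusted p under 0.05.

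In HET, 4 lists were called lower than in WT with camera, namely MHC class II presentation (median −0.72, adjusted p = 0.00248), MHC class I presentation (median −0.32, adjusted p = 0.00314), T and NK cell markers (median −0.08, adjusted p = 0.0148) and interferon response (median −0.14, adjusted p = 0.0375). With an estimated correlation the adjusted p was 0.931 for each of them, and with fry 0.999. Without WT replicate 1, no list was called lower and the interferon list was called higher (median 0.22, adjusted p = 0.0372 with camera). The 4 lists became 1 without HET replicate 2, 2 without HET replicate 3 and 1 without HET replicate 4. No member of these lists passed singly, over all targets or when adjusted over the list alone. The median HET minus WT difference of the interferon list was −0.60 in litter 1, −0.02 in litter 2 and 0.02 in litter 3, and that of T and NK markers −0.52, −0.29 and 0.074. For MHC class II it was −1.45, −0.12 and −0.75, and for MHC class I −0.69, −0.053 and −0.20. In litter 3 alone, which does not hold WT replicate 1, both MHC lists were called lower (adjusted p = 2.76e-07 and 0.0199 with camera).

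The comparison of KO with HET asks what separates the loss of both copies from the loss of 1. The 5 largest increases were those of the interferon-induced genes Ifi44l, Ifi44 and Cxcl9, at 42.6-fold, 27.9-fold and 22.6-fold, of Gzma, a granule protease of cytotoxic lymphocytes, at 18.4-fold (log2 4.20 ± 0.85, adjusted p = 0.0167 in limma), and of Cxcl10, at 17.4-fold. The largest decreases were Wnt5a (log2 −3.22 ± 0.40), Dclk1 (−2.93 ± 0.57), Fgf1 (−2.04 ± 0.44), Col4a5, a basement membrane collagen (−1.93 ± 0.41), and Map2k6 (−1.80 ± 0.32). Under the common floor Col4a5 did not pass (log2 −0.55, adjusted p = 0.103 in limma). The log2 change of Ifi44l went from 5.41 to 4.21 under it, that of Cxcl9 from 4.50 to 3.425 and that of Gzma from 4.20 to 3.38. Cxcl10 went from 4.12 to 2.72, and Wnt5a and Dclk1 were at −1.84 and −2.17. In all, 71 targets passed, 51 higher and 20 lower in KO. With litter as a block 116 passed, 92 higher and 24 lower. The median over all targets was 0.06, and −0.08 after quantile normalization and −0.09 after median centring. After quantile normalization the split was 57 higher and 65 lower, and after median centring 46 and 30. The count was 111 without WT replicate 1, which enters only through the shared spread, 19, 44 and 23 without HET replicates 2, 3 and 4, and 36 without KO replicate 2. It was 43 with sex as a covariate, 6 without the 2 male mice, 37 in litter 3 alone and 5 with the Benjamini-Yekutieli adjustment.

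Of the 34 interferon response genes 19 rose over all targets in KO against HET and 30 when adjusted over the list alone (median 1.93), and 29 over all targets with litter as a block. camera called 6 lists higher, with adjusted p-values of 1.13e-20 for interferon response, 2.37e-04 for T and NK cell markers, 3.72e-04 for MHC class I, 0.0032 for MHC class II, 0.00652 for cytokines and chemokines and 0.045 for NF-kB and TNF signalling. After median centring the median of the T and NK list turned from 0.41 to −0.008 and that of the NF-kB list from 0.17 to −0.01, and under the common floor the T and NK median was 0.061 and that of cytokines and chemokines 0. The adjusted p was 0.602 with an estimated correlation for the first 5 lists and 0.669 for the last, and only the interferon list passed in fry (adjusted p = 0.0166). With litter as a block the NF-kB list no longer passed (adjusted p = 0.0769 with camera), while the MHC class I and STAT3-linked lists passed in fry (adjusted p = 0.0314 for each).

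Of the 48 targets called against WT, 46 were also called against HET in the same direction. Independent lists of these sizes would share 1.33 higher and 0.17 lower targets, but lists that rest on the same KO mice are not independent. Simulated unchanged groups shared 0 calls, which decides nothing because such groups give hardly any calls. Because both comparisons use the same KO mice, the correlation of 0.93 across targets is set beside 0.50 in simulated unchanged groups, and the covariance of 0.49 beside 0.07. With separate pairs of KO mice in the comparisons, the covariance lay between 0.35 and 0.41 over 6 splits.

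The HET mice lay on the WT side of the range spanned by KO and WT. Over the 48 targets called in KO against WT, the HET mean lay below the midpoint of KO and WT, in the direction of WT, by a median of log2 1.04, with all 48 targets on the WT side. The WT mean itself lay a median of 0.86 below the midpoint. Of the 48, 40 passed when this contrast was adjusted over these targets alone, and none passed over all targets. The HET mean lay beyond the WT mean, away from KO, for 33 of the 48. This count and the 0.86 include WT replicate 1, which lay toward the KO mice on the first principal component. Neither was taken without that mouse. The median for single HET mice was −0.62 in replicate 1 and between −1.04 and −1.01 in the other 3. Without WT replicate 1, 114 targets were called in KO against WT and the median became −0.68, and without HET replicate 4 it was −0.85 over 27 targets.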

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

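The tests on the lane of KO replicate 3, on litters, on the T and NK score as a covariate, on the share of epithelial cells and on the lists lower in HET were chosen after the results they rest on had been seen; those on other splits and on a wrong label were not, although the place of WT replicate 1 near the KO mice on the first principal component was known. A mouse was picked out where it stood further from the other 3 of its genotype than chance gives in about 1 of 20 groups of normally distributed values. Of 297 groups of values 50 had such a mouse, and 23 of the 50 were WT replicate 1. The number by chance would be 14.8 for independent normal groups. Gene counts entered on their linear scale and many of the genes move together, so 14.8 is no exact expectation and the 23 are not separate observations.

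WT replicate 1 stood apart in its interferon list score, at 1.26 against −0.58 to −0.33. It had the highest normalized counts of its group for Ifi44l (444.4), Ifi44 (1104), Cxcl9 (238.7), Cxcl10 (191.4), Isg15 (1808), Ccl8 (62.8), Sp100 (265.4), Stat2 (982.5) and Socs1 (643). The same held for Psmb8 (5358), Psmb9 (1179), H2-D1 (23110), B2m (63740), Ciita (405.3) and H2-DMb2 (106), and for Pim1 (47.8), Icam1 (48.4), Gzmb (109.9) and Cd14 (550.5). Its C1qa was the lowest, at 325.1. Its codeset A total was the highest WT value, at 450400, and its share of codeset B targets at the floor the lowest, at 5.9%. HET replicate 1, of the same litter, stood above the other HET mice for Ifi44l (121.4), Ifi44 (400.3), Cxcl9 (72.2), Cxcl10 (73.2), Sp100 (181.6), Psmb9 (413.3), H2-DMb2 (43.1), Stat2 (608) and Cd14 (382.1).

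A wrong genotype label for WT replicate 1 was tested on targets called between KO and HET, where this mouse enters only through the shared spread. Over the 51 targets higher in KO, it lay at a median of 0.63 on the way from the HET mean (0) to the KO mean (1), and the other WT mice between −0.11 and −0.03. Over the 20 targets lower in KO it lay at 0.28, the other 3 between 0.01 and 0.20, which argues against a KO mouse under a WT label. None of the 4 lists lower in HET was called lower without this mouse; in litter 3 alone, which does not hold it, 0 of the interferon and T and NK lists but 2 of 2 MHC lists were called lower, so whether the MHC lists rest on it stays open. Because WT and HET replicate 1 share litter 1 and both had raised interferon transcripts, a difference between litters, such as an infection or inflammation, may lie behind it, a hypothesis left open because litter 1 held only 1 mouse per genotype.

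The rise of interferon transcripts in KO was weighed against 3 other explanations. The sparse lane of KO replicate 3 is argued against, because the mean list shift was 1.84 ± 0.47 (SE) without that mouse and 1.74 ± 0.42 with it. A difference between litters as the whole source is argued against by a shift of 1.93 ± 0.16 among the 4 KO and WT mice of litter 3, although 1 of these was male. With the T and NK marker score of each mouse as a covariate the shift was 0.90 ± 0.37 (camera adjusted p = 1.99e-15, and adjusted p = 0.36 with an estimated correlation), but no single target passed in limma and 8 members passed over the list alone instead of 29, for a reason that was not tested. The score is an imperfect measure of the share of these cells, since only 15 of its 29 markers had a mean of at least 20. The shift left after adjusting for it cannot decide whether more T and NK cells are the whole source. That question, whether interferon transcripts or T and NK cells drive the shared part, and the genotype itself stay open.

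The rise of T and NK markers may reflect fewer epithelial cells in the preparation, which would raise markers of every other cell type. Over members with a mean of at least 20, T and NK markers rose by 1.12 ± 0.36 and stromal markers shifted by −0.68 ± 0.45, monocyte and macrophage markers by 0.49 ± 0.27, neutrophil and mast cell markers by 0.26 ± 0.31, B and plasma cell markers by −0.015 ± 0.33 and the only endothelial marker by 0.47 ± 0.47. The difference of 1.79 ± 0.52 between T and NK and stromal markers argues against that explanation for the whole rise. The sparse lane of KO replicate 3 is argued against too, since the shift of the whole list was 0.58 ± 0.29 without it and 0.67 ± 0.26 with it. More lymphocytes within the epithelium and a changed state of the same cells were not told apart by any test here.

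In KO against WT 1 of 35 splits of the 8 mice, the real one, gave at least 48 targets, and the highest other split gave 15. In KO against HET 1 of 35 splits, again the real one, gave at least 71, and the highest other gave 2. A share of 1 of 35 is the smallest these splits can give, and they ignore the litters. They argue against chance for the 2 counts of targets but do not exclude it. For HET against WT the count was 0, so all 35 splits had to give at least as many and the comparison decides nothing; the highest other split gave 1. Chance cannot be excluded for the number of lists called with the preset correlation. In KO against WT 19 of 35 splits gave at least 4 lists, with up to 10 in another split, and in HET against WT 11 of 35 did, with up to 8. Such numbers of lists in arbitrary splits may reflect structure shared by the members of a list within mice. In KO against WT they may also reflect genotype, which some splits still part unevenly. The split with 10 lists set WT replicate 1 and KO replicates 1, 2 and 4 against the other mice. The 12 splits that part the litters as the real ones do are too few for a share under 0.05, so they cannot exclude chance. Among them the real counts were 48 for KO against WT and 71 for KO against HET, and the highest other counts 1 and 2.

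Other values that stood apart were these. KO replicate 3 had a scaling step of 5.65 in codeset A and 4.11 in codeset B. In that mouse Wnt5a, Ret and Col4a5 had a value of 5.65, the floor of its lane, above the other KO mice, and Stk26 was at 61.6 and Flt4 at 94.5. KO replicate 1 was high for Sp100 (770.6), DEFA6 (573), DEFA5 (126.3) and Mmp7 (44.8). KO replicate 2 was high for Thbs1 (33.5) and Socs1 (701.6). KO replicate 4 was low for Cd7 (102.1). HET replicate 4 had the highest Wnt list score of the HET mice, 0.31. WT replicate 2 had the highest endothelial list score of the WT mice, 0.14. Nos3 was at 3.85 in WT replicate 4 and at 2.27 in HET replicate 2, near the floor.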

How the results depend on the processing

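The settings of a common floor, of KO replicate 3 and WT replicate 1 both left out and of members matched by accession were chosen after seeing the data. The count for HET against WT was 0 under every alternative, including each mouse left out (0 to 0). Of 88 gene comparisons 85 kept their direction in every setting or had a difference of 0, as Cxcr4 did under the common floor, and these 85 include the 39 that had passed. The other 3, none of which had passed, are endothelial markers in KO against WT. Flt4 turned to −0.047 without KO replicate 3 (up to 0.67 over other single mice) and −0.064 without KO replicate 3 and WT replicate 1, Vwf to −0.235 after median centring, and Nos3 to −0.041 after quantile normalization and −0.003 without those 2 mice. The calls were less stable than the directions. In KO against WT the call was lost in 20 of 29 settings for Dclk1, 18 of 29 for Fgf1 and 17 of 29 for Cd8a. For Ifit1 it was lost in 2 of 29. For KO against WT the count of 48 became 81 after quantile normalization, 86 with litter as a replicate block, 9 with sex as a covariate, 1 without the males, 3 with only the 2 groups, 188 with array weights, 0 with Benjamini-Yekutieli, 4 in codeset A alone and 125 without KO replicate 3 and WT replicate 1, a setting chosen after seeing the data. Leaving out 1 mouse gave 7 to 114. For KO against HET the 71 became 122, 116, 43, 6, 134, 5 and 14 under the same settings except only the 2 groups, 37 in litter 3 alone, and 132 without those 2 mice, with 19 to 111 over single mice. The HET position of −1.04 became −0.83 with a pseudocount of 10, −0.51 after quantile normalization, −0.25 without the males (1 target), −0.49 with array weights, −0.31 in codeset A alone, −0.82 with a common floor and −0.62 without those 2 mice, with −1.30 to −0.68 over single mice. It is taken over the targets called in each setting, which differ. The 4 lists for KO against WT became 1 after median centring, 2 without the males, 0 in codeset A alone, 2 in codeset B alone, 7 without those 2 mice, 0 with an estimated correlation and 1 with fry, with 2 to 5 over single mice. The 4 lists for HET against WT became 2 with a minimum mean of 20, 1 in codeset A alone, 2 with a common floor, and 0 without those 2 mice, with an estimated correlation and with fry, with 1 to 5 over single mice. In HET against WT the interferon median turned to 0.22 without WT replicate 1, alone or with KO replicate 3 (−0.34 to 0.22 over single mice), and the T and NK median to 0.054 in the same settings and 0.074 in litter 3 alone (−0.19 to 0.054 over single mice). Fewer mice or targets were tested in the subsets. The cause of the other changes was not tested. The litter block added the MHC class II list for KO against WT and ended the NF-kB call for KO against HET, and changed no other list call in camera. In fry it added the MHC class I and STAT3-linked lists for KO against HET. The consolidated table and Ptpn2 were not run. Targets near the floor, mostly in codeset A, are limited by low counts.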

Other observations

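Markers of Paneth cells varied widely between mice of one genotype. The list score lay at 0.50 in KO replicate 1 and between −2.30 and −1.48 in the other 3 KO mice, at 0.89 and 0.47 in HET replicates 1 and 3, and at −2.32 and −1.96 in HET replicates 2 and 4. The WT mice lay between −0.42 and 0.53. The exact permutation p of KO against WT was 0.114. HET replicates 3 and 4 were of the same litter, so the markers also differed between littermates of one genotype.

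Of lists not described so far, none passed in KO against WT with camera. Antimicrobial and host defence genes had a median change of 0.15 and a mean of −0.16 over 12 members, of which 2 rose when adjusted over the list alone and 1 over all targets with litter as a block, and the median turned to −0.23 after median centring. Autophagy genes had a median of −0.21 over 9 members, and −0.56 after median centring, and 1 member rose when adjusted over the list alone. Iron handling genes had a median of −0.08 over 5 members, and −0.38 after median centring. Apoptosis genes had a median of 0.06 over 24 members, of which 2 passed with litter as a block, and it turned to −0.12 after quantile normalization and −0.08 after median centring. Notch genes had a median of −0.09 over 21, and −0.21 after median centring, and TGF-beta and BMP genes of −0.002 over 33, and −0.038 after median centring. Of the TGF-beta and BMP genes only Thbs1 passed. The 5 lists with fewer than 5 measured members, for absorptive, goblet, enteroendocrine and tuft cells, junctions and matrix metalloproteinases, were not tested, and Dclk1 was their only member to pass in limma. Among their members, chosen after their values were seen, Cdh1, the epithelial cadherin, had a log2 change of 0.22 ± 0.15 in KO against WT, MUC2, the goblet cell mucin, −0.31 ± 0.34, Chga, an enteroendocrine marker, −0.39 ± 0.17 and Mmp7 −1.33 ± 1.07, none past the threshold.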
